A study of Homo sapiens with 275 samples.

How the data were processed

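The series measured RNA in regions of fixed human tissue sections with the GeoMx Digital Spatial Profiler, in which probes carrying a barcode are hybridised to the section, the barcodes of a chosen region are released by light, and the collected barcodes are sequenced. Per the labels' protocols, sections were hybridised with a whole-transcriptome set of human probes and stained for pan-cytokeratin, p53 and CAPS, regions were chosen on the fluorescence images under a pathologist's supervision, and the barcodes of each region were collected into a well of a plate. The 275 regions come from 16 case codes on 4 plates. They cover epithelium and stroma of the fallopian tube and of omental metastases.

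Per the file headers, each deposited file holds whole-number counts per probe identifier, made with the GeoMx NGS pipeline 2.3.3.10, which trimmed and stitched the reads, aligned them to the probe barcodes and counted each unique molecular identifier once per probe. The submitters' processing notes name the build GRCh38 (patch p13), and no coordinate of it is used here. The counts were deposited per region, with no normalization and no pooling. All 275 files hold the same kind of counts. In 64 of them the header lines do not let the count column be named apart from a quality value, so these were recorded under a different unit name and used as counts like the other 211. The files used here list 18815 probe identifiers and do not pair them with gene names, and no table that does was used here. Probes are therefore given by their identifiers, at most 2 that rose and 2 that fell per comparison. The gene lists fixed before the data were examined (ciliated, secretory, cell cycle, p53 targets, matrix, immune and others) were not tested for the same reason.

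Groups were taken from the titles. A donor is a case code. Regions with fewer than 1000 raw reads, under 80% of reads aligned or a sequencing saturation under 50% were left out, by limits set before the data were examined. This kept 255 regions. All 20 regions left out failed on alignment and lie on 1 plate. One donor lost all of its normal stroma, so the comparison of STIC with normal stroma has 5 pairs and not the 6 planned. No pair of regions of the same donor and group held identical counts among 675 pairs compared, and the lowest chi-square per degree of freedom was 1.04, with a median of 1.72, so no region was treated as deposited more than once.

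Counts of the regions kept were summed per donor and region type, since regions of 1 donor are not independent. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM scaling, the default filter on low counts, and Benjamini-Hochberg adjustment, and a probe passed at an adjusted p under 0.05. Only the groups compared entered each fit. Where both region types came from the same donors, the donor was a block. STIL was set against FOXJ1neg epithelium of other donors without a block. Metastases have case codes of their own, some of which share a number with a tube code. The labels do not say that a shared number is a shared donor, so these comparisons were fitted without a block, and with the number as a block as an alternative. Named probes passed the test, changed in the same direction in every pair (or did not overlap between unpaired groups), had a mean log2 CPM of at least 5, and had the largest rise or fall. CPM in the text are counts scaled to the usual CPM unit with the total of each sum over all probes and the TMM factor of the fit, while the mean log2 CPM for naming is that of the probes in the fit. Some numbers of passing probes are given as a percentage of the 18815 probes on the panel, and for STIC against FOXJ1neg these percentages stand for 169 probes higher and 52 lower. Log2 fold changes come from the fit and weight sums by their counts, so they can differ from the ratio of mean CPM. SD are over donors, except where the text names sums, regions or probes. SE of log2 changes come from the F test of the fit, which shares information between probes, and are no spread over donors.

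Pairing was checked on the correlation of deviations from the group means over 2495 probes with a mean log2 CPM of at least 6. In the comparisons paired by donor code, the median correlation of sums of the same donor lay between 0.0891 and 0.494, and that of different donors between -0.112 and -0.0319. The lowest single pair was -0.0094, in the stroma of invasive carcinoma and STIC. For metastasis against STIC epithelium, the 3 pairs with a shared case number had correlations from 0.353 to 0.7, each the highest for that metastasis. The result with that block is therefore given beside the main result. For metastasis against invasive carcinoma only 2 numbers are shared, in epithelium (0.576 and 0.803) and in stroma (0.315 and 0.629).

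The level of non-specific counts was described by a floor, the mean CPM of the 4704 probes with the lowest mean rank. The floor share is the percentage of all counts that 18815 probes at that level would take. It describes the lowest probes and is no bound on background, which may be higher for other probes, and was chosen after the data were seen. Sets of probes were also built after the data were seen, from the probes past the threshold in a comparison of this series, and followed in other donors or tissue. A set's score is the mean log2 CPM of its probes minus the mean of all probes (prior count 2), its median change is given relative to the median of all probes, and its percentile is among 10000 random lists matched on mean expression. Score changes were tested with exact permutation tests, 2-sided (sign flips for pairs, regroupings otherwise), with Benjamini-Hochberg adjustment over the 26 set contrasts.

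The tests were checked on counts simulated from the fitted means and dispersions with 200 probes changed. These were drawn from the probes with a mean fitted count of at least 20, so recovery of probes with lower counts was not simulated. At a log2 change of 1, the STIC against FOXJ1neg design recovered 152 of 200 probes with 6 false calls among 18792 probes. The design of invasive carcinoma against STIC recovered 191 with 34 false calls among 18815. The p53 signature design recovered 0 of 200 at a log2 change of 1 and 173 of 200 at 2, among 16146. The metastasis against invasive epithelium design recovered 108 of 200 at 1, among 18815. The series interaction recovered 8 of 200 at 1 and 168 of 200 at 2, among 18792.

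The alternatives fixed before the data were examined were upper quartile scaling, DESeq2 1.42.0, the mean of log2 CPM per donor with limma 3.58.1, no filter on low counts, all 275 regions, each donor left out in turn, no donor block, one fit over all sums of a compartment, the shared case number as a block, and plate as a term. A random donor block for STIL could not be estimated, since 1 donor is in both groups. Added after the data were seen were subtraction of the floor (pseudocount 50, limma), the log floor as a term, thinning of every sum to the smallest total of the comparison, use of sums of at least 100000 counts only, and for STIL the FOXJ1neg sums of the same plate only.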

Results

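High-grade serous carcinoma (HGSC) of the ovary is thought to arise in the epithelium of the fallopian tube, and the series sampled the lesions along that path. The p53 signature is a stretch of benign-looking epithelium with abnormal p53 staining, the serous tubal intraepithelial lesion (STIL) shows atypia short of carcinoma, and the serous tubal intraepithelial carcinoma (STIC) is a non-invasive carcinoma. Regions of these lesions were captured together with invasive carcinoma, omental metastases, normal stroma, and tube epithelium that the labels divide into FOXJ1pos and FOXJ1neg. FOXJ1 is a transcription factor of multiciliated cells. The case codes fall into series that the labels call p53, STIL, STIC and HGSTIC, of which HGSTIC holds every invasive carcinoma and every metastasis. After quality filtering, epithelium comprised 30 FOXJ1neg and 35 FOXJ1pos regions of 10 donors each, 7 p53 signature regions of 3 donors, 13 STIL regions of 2 donors, 35 STIC regions of 8 donors, 20 invasive regions of 4 donors and 31 metastasis regions of 3 case codes. Stroma comprised 22 normal regions of 7 donors, 21 STIC regions of 8, 10 invasive regions of 4 and 29 metastasis regions of 3, with a single region each beside a p53 signature and a STIL.

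A region held 12338 to 7667637 counts, with a median of 239591 over all regions. Among the regions kept, the median was 92200 counts in FOXJ1neg epithelium, 737071 in STIC epithelium, 1548179 in metastasis epithelium and 66980 in normal stroma. The floor share, the percentage of counts that a uniform level set by the 4704 lowest-ranked probes would take, was 50.6 ± 6.29% in FOXJ1neg (SD, n = 10 donors), 54.2 ± 5.65% in FOXJ1pos (n = 10), 42.7 ± 8.29% in STIC (n = 8) and 39.9 ± 6.77% in invasive epithelium (n = 4). It was 57 ± 7.14% in normal stroma (n = 7) and 52.4 ± 8.6% in STIC stroma (n = 8). Fold changes of probes near the floor can therefore understate changes of their targets.

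**Figure D1:**
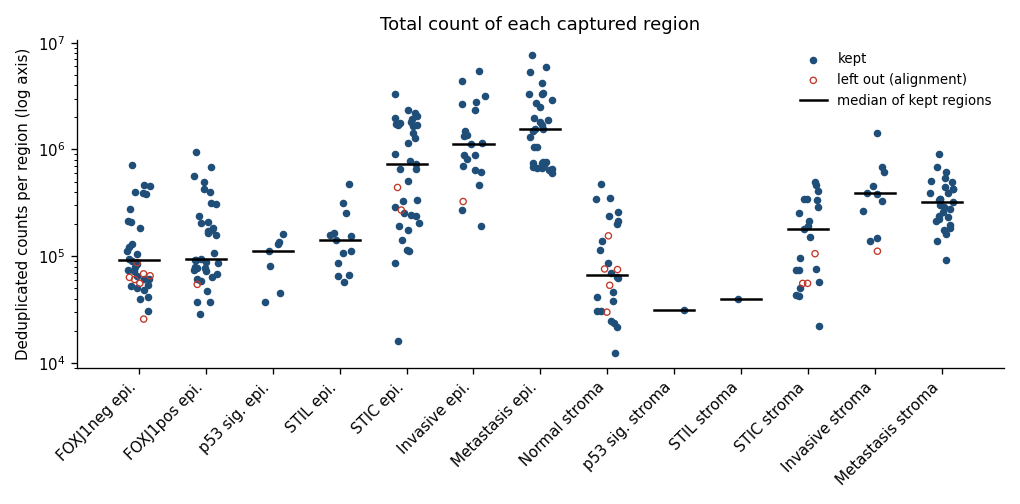
Deduplicated counts of each region (log axis) by region type, with regions left out for low alignment as open circles and the median of the regions kept as a line. The medians are 92200 in FOXJ1neg and 737071 in STIC epithelium.

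Epithelium and stroma were compared within STIC lesions. Of 18790 probes tested in 8 donor pairs, 1567 were higher in STIC epithelium and 865 were higher in the stroma beside it. RTS0029718 was the probe with the largest epithelial excess, at 1200 ± 725 CPM in epithelium and 78.9 ± 31.4 in stroma (SD, n = 8 pairs), a log2 change of 3.71 ± 0.304 (SE, adjusted p = 4.68e-11). RTS0027030 followed with a log2 change of 3.12 ± 0.276. The largest stromal excess was that of RTS0027552, at 55.2 ± 9.42 CPM in epithelium and 563.3 ± 244.8 in stroma (log2 change -3.29 ± 0.229, adjusted p = 1.85e-12), and then of RTS0026754 (log2 change -3.07 ± 0.214). Metastases gave sets of compartment probes from other tissue, 814 higher in metastasis epithelium than in metastasis stroma and 776 lower, in 3 pairs. In STIC lesions 91.6% of the epithelial set and 18.4% of the stromal set were higher in epithelium, and each score moved the same way in 8 of 8 pairs (exact permutation p = 0.00781, the smallest possible, adjusted p = 0.0677). The 3 metastasis codes share numbers with tube codes that have STIC regions, so these sets are from other tissue but perhaps not from other donors. Sums of epithelium were deeper than those of stroma in 8 of 8 pairs, by a median of 11.7 times, with a floor share lower by 9.71 ± 3.8 points, and with the floor as a term 65 probes passed, 58 of them among the 2432. The floor share was lower in every pair, so that term also takes up part of the difference between epithelium and stroma. Without the pairing by donor 994 passed, and leaving out 1 donor of the HGSTIC series gave 1269.

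FOXJ1pos epithelium was compared with FOXJ1neg epithelium of the same 10 donors. It had 663 probes higher and 772 lower of 17508 tested. The largest rises were those of RTS0035911, at 760.6 ± 236.8 CPM in FOXJ1pos and 126.5 ± 53.7 in FOXJ1neg (SD, n = 10 pairs, 5.98-fold, log2 change 2.58 ± 0.139 SE, adjusted p = 7.88e-37), and RTS0032033, at 785 ± 313.4 against 133.6 ± 82.7 CPM (log2 change 2.53 ± 0.141). The falls were smaller. RTS0050927 fell from 223.2 ± 93.3 to 99.4 ± 42.9 CPM (log2 change -1.12 ± 0.114, adjusted p = 2.33e-15) and RTS0024875 from 58.7 ± 24.7 to 28.9 ± 12.3 CPM (log2 change -1.06 ± 0.141). Among probes that passed with at least a 2-fold change, 94.9% were higher and only 8 probes were lower. The labels name these regions by FOXJ1, while the stains given in the protocols are pan-cytokeratin, p53 and CAPS. The probes for FOXJ1 and CAPS cannot be picked out without gene names. A rise of either could follow from how the regions were chosen and would be no finding. The floor share was higher in FOXJ1pos in 10 of 10 pairs, by 3.68 ± 1.95 points (SD), and the epithelial set of the metastases was lower in 9 of 10 pairs (score change -0.145 ± 0.133, exact permutation p = 0.00391, adjusted p = 0.0677). With the floor as a term, 77 probes passed, 72 of them among the 1435. Since the floor moved one way in every pair, that term also takes up part of the difference between region types. The number was 764 with DESeq2, 454 with limma on mean log2 CPM, 509 without the donor block and 790 without 1 donor of the HGSTIC series.

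**Figure D2:**
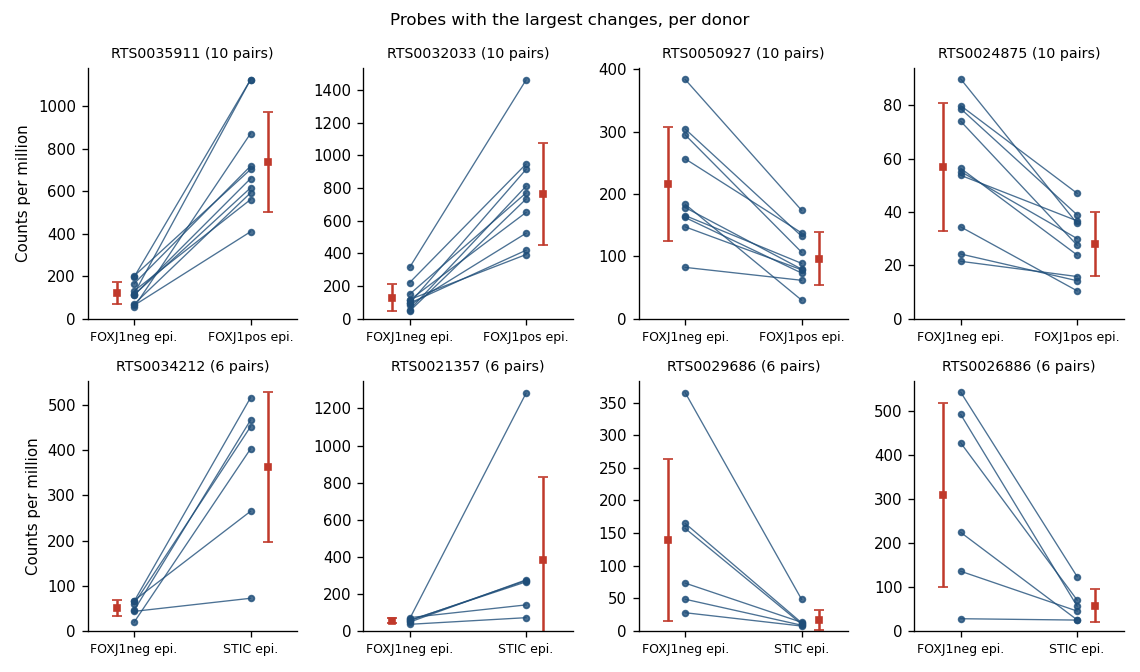
CPM of the named probes per donor, with lines joining the region types of 1 donor and squares giving the mean and SD over pairs, for FOXJ1pos against FOXJ1neg (10 pairs) and STIC against FOXJ1neg (6 pairs). CPM are scaled here over all sums and differ slightly from those in the text, and every line of a probe runs the same way.

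The p53 signature was compared with FOXJ1neg epithelium of the same 3 donors, which asks what differs in the earliest of the lesions. A single probe of 16146 passed. RTS0029686 was 7.19-fold lower, at 58.4 ± 31.1 CPM in the p53 signature and 482.9 ± 147.5 in FOXJ1neg (SD, n = 3 pairs, log2 change -2.85 ± 0.516 SE, adjusted p = 0.0276). At an unadjusted p under 0.05 there were 498 probes, fewer than 5% of those tested. The same probe was the only call with DESeq2, with limma and with upper quartile scaling. The deepest p53 signature sum held 539033 counts and the shallowest 37228, and after thinning to that total no probe passed, with under 1% of the panel left to test. The number was 1, 2 or 4 with 1 donor left out, and 2 without the donor block. Without either of 2 of the 3 donors RTS0029686 did not pass (log2 change -2.79 and -3.22, adjusted p = 0.0754 and 0.104).

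STIL epithelium of 2 donors was compared with FOXJ1neg epithelium of 9 other donors. It had 17 probes higher and 1 lower of 18727. RTS0035201 was at 73.9 ± 25 CPM in STIL (SD, n = 2) and 17.7 ± 23.2 in FOXJ1neg (n = 9, log2 change 2.22 ± 0.412 SE, adjusted p = 0.00319). RTS0027277 was at 245.4 ± 209.6 against 52.2 ± 27.4 CPM (log2 change 2.21 ± 0.302). The probe that was lower was RTS0032485, at 22.6 ± 6.68 against 57.8 ± 26.2 CPM (log2 change -1.33 ± 0.297, adjusted p = 0.0394). Both STIL donors lie on 1 plate, and most of the FOXJ1neg donors on others. Against the 2 FOXJ1neg donors of the STIL plate 4 probes passed, none of them named here. The log2 changes were then 0.752 for RTS0035201, 1.72 for RTS0027277 and -0.464 for RTS0032485 (adjusted p = 0.661, 0.291 and 0.843). RTS0035201 goes with the plate over all region types. It averaged 40.2 ± 13.3 CPM (SD, n = 10 sums) and 48.4 ± 18 (n = 13) on 2 plates, and 3.13 ± 4.18 (n = 20) and 2.8 ± 4.14 (n = 21) on the others. The FOXJ1neg sum of 1 STIL donor was not in the comparison, and was at 55.5 CPM for RTS0035201, 157.2 for RTS0027277 and 20.8 for RTS0032485. Against all 9 donors 4 probes passed with DESeq2, 0 with limma, against 985 at an unadjusted p under 0.05 in edgeR. Without 1 of the STIL donors 1 probe passed, where the lone sum is assumed to vary like the others.

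STIC epithelium was compared with FOXJ1neg epithelium of the same 6 donors, the step from benign epithelium to carcinoma in place. Of the 18815 probes on the panel, 0.898% were higher in STIC and 0.276% (52 probes) lower. RTS0034212 rose in 6 of 6 pairs, from 49.4 ± 18 CPM in FOXJ1neg to 360.8 ± 166.1 in STIC (SD, n = 6, 5.81-fold, log2 change 2.54 ± 0.345 SE, adjusted p = 2.92e-05), and RTS0021357 rose from 55.2 ± 12.7 to 384 ± 449 CPM (log2 change 2.32 ± 0.391). RTS0029686, the probe that was lower in the p53 signature, was 7.23-fold lower in STIC, at 17 ± 15.4 against 136.6 ± 122.5 CPM (log2 change -2.85 ± 0.245, adjusted p = 2.15e-10). RTS0026886 fell from 300.0 ± 201.7 to 57.5 ± 36.5 CPM (log2 change -2.32 ± 0.289). Of the higher probes, 68 (40.2%) were also higher in metastasis epithelium than in metastasis stroma, where independent lists would share 4.33%, and of the 52 lower probes 11 were higher in metastasis stroma, where 2.15 would be shared. These expectations are not matched on abundance. The stromal set was lower in STIC than in FOXJ1neg in 6 of 6 pairs, by a score of -0.0954 ± 0.0483 (SD), and the epithelial set was higher in 6 of 6, by 0.325 ± 0.311 (exact permutation p = 0.0312 for each, the smallest possible, adjusted p = 0.116). STIC sums were deeper in 6 of 6 pairs, by a median of 10.9 times.

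The share of the panel that passed in STIC, 1.17% in the main fit, depended on the fit. It was 1.31% with DESeq2, with 57.5% of those probes shared, and 1.84% (347 probes) with all regions kept. Only 2 probes passed with limma on mean log2 CPM and 49 without the donor block, and a fit over all epithelial sums gave 929. With sums thinned to the smallest total 22 passed. With the floor as a term 1.1% of the panel passed and the balance turned, to 0.229% higher and 0.872% lower. Leaving out 1 donor of the STIC series gave 62 probes, leaving out the donor with the shallowest FOXJ1neg sum gave 0.569% of the panel, and subtracting the floor gave 91 probes, 83 of them also in the main fit.

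**Figure D3:**
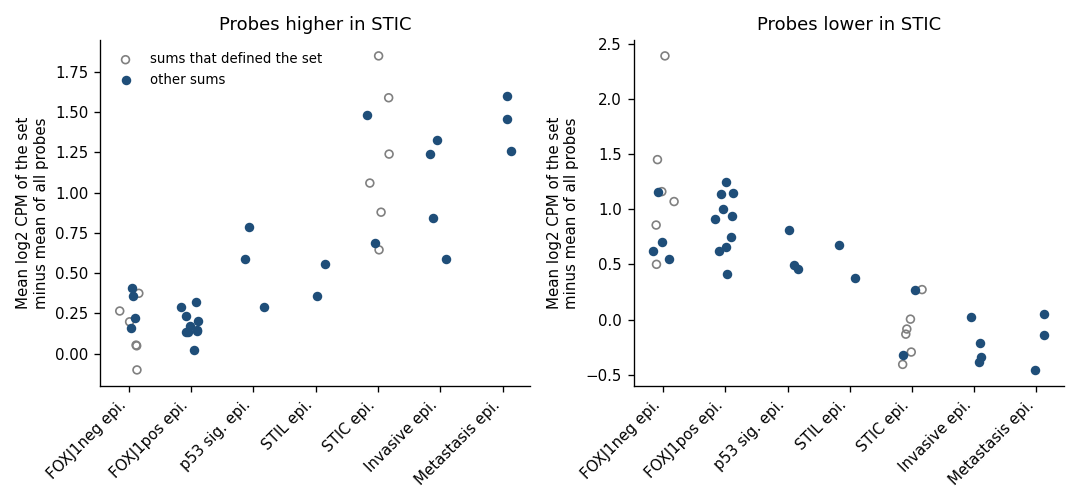
Score of the probes higher in STIC (left) and of the 52 probes lower (right) in each donor sum of epithelium, as mean log2 CPM of the set minus the mean of all probes. Open circles are the 12 sums that defined the sets and filled circles are sums that did not. Metastases average 1.44 and -0.183, and p53 signatures 0.554 and 0.59.

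The STIC probes were followed in sums that had not defined them. In invasive carcinoma of 2 donors, against FOXJ1neg epithelium of 4 others on other plates, 85.2% of the probes higher in STIC were higher, as were 9.62% of the 52 probes lower in STIC, with median changes of 0.557 and -0.794 (exact permutation p = 0.0667 for each score, the smallest possible, adjusted p = 0.193). In metastases the shares were 97.6% and 9.62%, with medians of 1.15 and -0.771 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.116). Both metastasis scores moved the same way in 3 of 3 case codes, of which 2 share a number with a donor that helped define the sets. In STIL, against FOXJ1neg of 3 other donors, 67.5% of the higher set and 32.7% of the lower set were higher, with medians of 0.172 and -0.288 (exact permutation p = 0.3 and 0.5, where 0.1 is the smallest possible). In the p53 signature the shares were 61.5% and 30.8% and the medians 0.176 and -0.318. The lower set was lower in 3 of 3 p53 signature pairs and the higher set was higher in 2 of 3 (exact permutation p = 0.25 and 0.5, where 0.25 is the smallest possible).

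RTS0029686, which passed in both comparisons, was followed over all region types. It averaged 234.6 ± 197.8 CPM in FOXJ1neg (SD, n = 10) and 179.6 ± 141.2 in FOXJ1pos epithelium (n = 10), 56.2 ± 30.6 in the p53 signature (n = 3) and 169.6 ± 63.5 in STIL (n = 2). It was at 14.8 ± 13.9 CPM in STIC (n = 8), 10.3 ± 1.86 in invasive carcinoma (n = 4) and 18.3 ± 2.22 in metastasis epithelium (n = 3), with 33.7 ± 25.9 in normal stroma (n = 7). Stroma beside STIC was at 15.2 ± 13.9 CPM (n = 8), invasive stroma at 10.3 ± 3.03 (n = 4) and metastasis stroma at 20.5 ± 3.45 (n = 3). Before TMM scaling the floor was at 17 to 30 CPM in STIC, 16.8 to 25.6 in invasive and 18.2 to 26.7 in metastasis epithelium. The means there lie near or below it, as do those of these stromas and normal stroma, so differences among them cannot be read as expression. The single stroma regions beside a p53 signature and a STIL were at 48.2 and 41.8 CPM. Levels in FOXJ1neg ran from 28.2 to 623 CPM over donors. Over FOXJ1neg and FOXJ1pos sums together the mean was 353.4 ± 149.2 CPM on the 2 plates of the p53 and STIL series (SD, n = 8 sums of 4 donors) and 109.5 ± 97.7 on the 2 plates of the STIC and HGSTIC tubes (n = 12 sums of 6 donors).

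**Figure D4:**
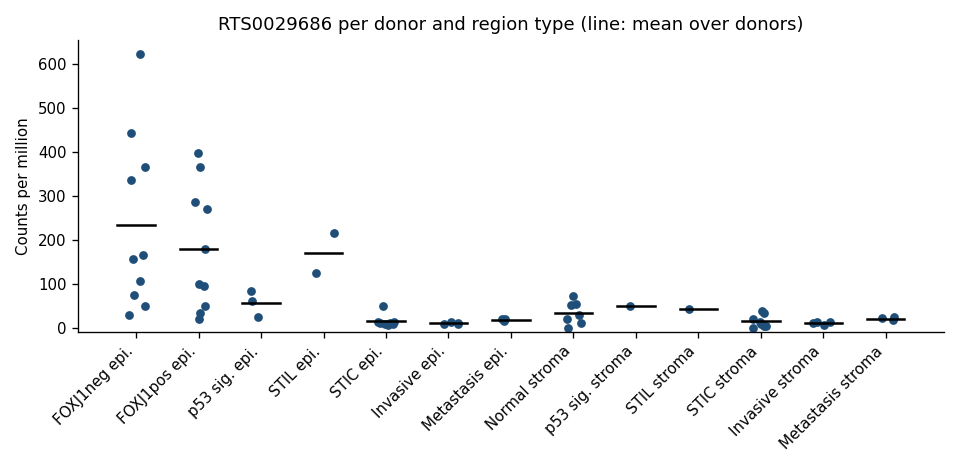
CPM of RTS0029686 in each donor sum (points) by region type, with the mean over donors as a line. The 8 STIC sums lie between 6.02 and 48.7 CPM and the 10 FOXJ1neg sums between 28.2 and 623.

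Invasive carcinoma was compared with STIC epithelium of the same 4 donors, the step from carcinoma in place to invasion. With edgeR 0 of 18815 probes passed, and 589 had an unadjusted p under 0.05, fewer than 5% of those tested. The smallest adjusted p was 0.359. Changes were small, with an SD of 0.161 over all log2 changes and a median SE of 0.132. The epithelial set of the metastases was higher in 2 of 4 pairs (score change -0.0105 ± 0.2) and the stromal set was lower in 2 of 4 (-0.0222 ± 0.0431). DESeq2 passed 2 higher and 11 lower, limma 0, and a fit over all epithelial sums 19.

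Metastasis epithelium of 3 case codes was compared with invasive carcinoma of 4 donors. With edgeR 1 of 18815 probes passed and was higher, and 3099 had an unadjusted p under 0.05. That probe, RTS0035201, lies under the abundance limit for named probes and was chosen after its values were seen. It was at 26.7 ± 4.03 CPM in metastases (SD, n = 3) and 3.82 ± 5.05 in invasive carcinoma (n = 4), with a fitted log2 change of 4.12 ± 0.347 (SE, adjusted p = 0.00426). It is the probe whose level goes with the plate over all region types, and in benign FOXJ1neg epithelium on the plate of the metastases it was at 44.5 CPM (1 donor). With plate as a term its log2 change was 0.0339 (adjusted p = 1), and 1 other probe passed. Every metastasis lies on a plate with no tube carcinoma, and the plate term rests on the benign tube of the single tube donor there. DESeq2 passed 445 probes, a block by shared case number, with 2 pairs, 772, and the floor as a term 0.537% of the panel.

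Against STIC epithelium of the 6 HGSTIC donors, metastasis epithelium had 12 probes higher and 0 lower in edgeR, with 2508 at an unadjusted p under 0.05. RTS0050382 was at 315 ± 230 CPM in metastases (SD, n = 3) and 35.8 ± 10 in STIC (n = 6, log2 change 3.15 ± 0.428 SE, adjusted p = 0.0104). RTS0020937 was at 351.7 ± 262.8 against 53.7 ± 9.9 CPM (log2 change 2.72 ± 0.41). Both probes are far higher in metastasis stroma, at 2446 ± 601 and 6124 ± 1985 CPM (SD, n = 3). Paired by the shared case number, 98 probes were higher and 4 lower, and all 12 were among them. DESeq2 passed 279 higher and 72 lower, limma 2, the fit with the floor as a term 382, and the fit with plate as a term 6, 2 of them among the 12, while leaving out 1 sum gave 2 to 45.

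The stroma beside STIC was compared with normal stroma of the same 5 donors. The shallow sums left 1780 probes to test, of which 21 were higher and 9 lower beside STIC. RTS0051029 was at 240.2 ± 166.1 CPM beside STIC and 79.2 ± 38.6 in normal stroma (SD, n = 5 pairs, log2 change 1.297 ± 0.231 SE, adjusted p = 9.83e-05), and RTS0037085 at 181.7 ± 142.5 against 71.8 ± 16.9 CPM (log2 change 1.28 ± 0.22). RTS0029190 was lower, at 179.3 ± 99.9 against 326.8 ± 90.8 CPM (log2 change -1.04 ± 0.227, adjusted p = 0.00223), as was RTS0050208 (log2 change -0.91 ± 0.215). The stromal set of the metastases was higher beside STIC in 4 of 5 pairs (score change 0.132 ± 0.143, exact permutation p = 0.125, adjusted p = 0.271) and the epithelial set in 3 of 5 (0.0131 ± 0.135). The floor share was lower beside STIC in 5 of 5 pairs, by 3.13 ± 2.38 points. With limma or without the donor block 0 passed, where edgeR had 7.42% of those tested at an unadjusted p under 0.05. Leaving out 1 donor gave 11 to 33, and the floor as a term left 6. That term also takes up part of the difference between these stromas, as the floor moved one way in every pair.

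The stroma of invasive carcinoma was compared with the stroma beside STIC in the same 4 donors. It had 3 probes higher and 8 lower of 18792. RTS0049645 was at 206.4 ± 218.2 against 51.4 ± 11.6 CPM (SD, n = 4 pairs, log2 change 1.28 ± 0.262 SE, adjusted p = 0.0355), and RTS0024090 at 117.3 ± 53.9 against 46 ± 13.1 CPM (log2 change 1.25 ± 0.203). RTS0051175 was lower, at 227.4 ± 31 against 829 ± 538 CPM (log2 change -1.66 ± 0.334, adjusted p = 0.0296), and RTS0038100 at 44.5 ± 19.7 against 136.2 ± 73.2 CPM (log2 change -1.48 ± 0.211). The stromal set of the metastases was lower in invasive stroma in 4 of 4 pairs, by a score of -0.123 ± 0.0489 (exact permutation p = 0.125, the smallest possible, adjusted p = 0.271). The epithelial set was higher in 3 of 4, by 0.0625 ± 0.106 (exact permutation p = 0.375, adjusted p = 0.609), and the floor share was lower in 3 of 4, with a mean change of -2.73 ± 2.92 points. Upper quartile scaling passed 1 higher and 8 lower, DESeq2 3, limma 0, and the fit without the donor block 0. Leaving out single donors gave 0, 0, 2 and 90.

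Metastasis stroma was compared with the stroma of invasive carcinoma, omentum against tube. It had 14 probes higher and 1 lower of 18815. RTS0032503 was at 72.6 ± 33.6 CPM in metastases (SD, n = 3) and 22.6 ± 6.9 in the tube (n = 4, log2 change 1.88 ± 0.33 SE, adjusted p = 0.0483), and RTS0036214 at 153.6 ± 26.6 against 48 ± 24.2 CPM (log2 change 1.85 ± 0.331). The probe that was lower was RTS0026955, at 31.5 ± 5.95 against 66.6 ± 11.9 CPM (log2 change -1.14 ± 0.205). The plate term rests on 1 tube donor here too. Upper quartile scaling passed 46, DESeq2 95, limma 0, the floor as a term 954 and plate as a term 3, while the block by shared number passed 0.553% of the panel, and leaving out 1 sum gave from 1 probe to 0.622% of the panel.

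The change from FOXJ1neg to STIC was compared between the 4 donors of the HGSTIC series and the 2 of the STIC series, with the difference itself tested. The signed log2 change was higher in the HGSTIC donors for 8 probes and lower for 353, of 18792. RTS0027590 differed by -3.81 ± 0.69 (log2, SE, adjusted p = 0.000498) and RTS0029718, the probe with the largest epithelial excess in STIC, by -3.77 ± 0.617 (adjusted p = 0.000153). With the floor as a term they differed by 2.92 and -0.449 (adjusted p = 1 for each), so the direction of RTS0027590 turned. The change of the floor share separates the series, at -12.5 to -10.3 points in the STIC series and -3.1 to 0.33 in HGSTIC. That term therefore overlaps the difference tested, and fits with it cannot decide on background. In the other direction RTS0036778 differed by 1.55 ± 0.398 (adjusted p = 0.0209) and RTS0033570 by 1.20 ± 0.348. The 353 probes changed by 1.44 ± 0.439 in the STIC series (mean log2, SD, n = 2) and by -0.108 ± 0.118 in the HGSTIC series (n = 4). They were picked for this difference in these same donors. Their mean FOXJ1neg level was also lower in the STIC series, at 5.25 and 5.41 log2 CPM, than in HGSTIC, at 5.77 to 6.03. Among the 353, 63 were higher in metastasis epithelium than in metastasis stroma, where independent lists, not matched on abundance, would share 15.3. The floor share fell by 11.4 ± 1.57 points from FOXJ1neg to STIC in the STIC series (SD, n = 2) and changed by -1.36 ± 1.82 points in the HGSTIC series (n = 4, exact permutation p = 0.0667 over 15 splits, the smallest possible). Leaving out 1 of the STIC series donors left 2 probes, and leaving out either of 2 HGSTIC donors left 46 (0.244% of the panel) or 0.622%, against 1.92% in the main fit. DESeq2 passed 0.925% of the panel, upper quartile scaling 0.818% and all regions 1.11%, while limma passed 0 probes and the floor as a term 2.

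**Figure D5:**
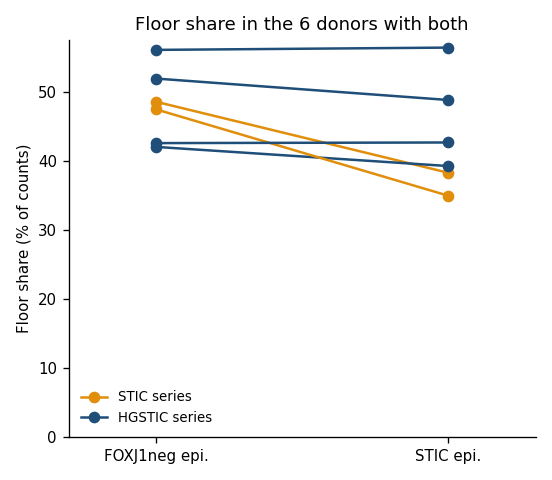
Floor share (percentage of counts) of the FOXJ1neg and STIC sums of each of 6 donors, joined by lines and coloured by series. The share falls by 11.4 points on average in the 2 STIC series donors and by 1.36 points in the 4 HGSTIC donors.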

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

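The tests of depth, background, stromal RNA and a single donor below were chosen after the results were seen, as were the sets they use, while the splits of the samples were planned. Values far from the rest were looked for in 46 groups of 4 to 10 values, of which chance alone would give about 5%, and 2 were found. In FOXJ1pos against FOXJ1neg, the change of RTS0050927 in 1 donor was -2.58, beside a nearest value of -1.46 and a range up to -0.411 (log2, n = 10 pairs). In the same comparison the score of the metastasis epithelium set changed by -0.486 in 1 donor, with the nearest at -0.191. The FOXJ1neg sum of that donor is a single region of 47802 counts, the shallowest of the FOXJ1neg sums, against 1205002 counts in its FOXJ1pos sum. The single stroma region beside a p53 signature scored 1.45 for the probes lower in FOXJ1pos epithelium (the set from donors without a p53 signature), above the 0.779 to 1.28 of the 7 normal stroma sums. Of 16 such scores of the 2 single stroma regions it was the only one above the range, and 4 lay below. For the probes higher in FOXJ1pos the p53 signature stroma scored -0.224 (set from donors without STIC, lowest normal -0.203) and -0.134 (set from donors without a p53 signature, lowest -0.0638). The stroma beside a STIL scored -0.137 for the latter set and -0.0519 for the probes lower in STIC (lowest normal 0.153). The regions beside the p53 signature and the STIL held 31380 and 39420 counts, fewer than any normal stroma sum (46717 to 1534370). An effect of depth on these scores cannot be told apart from the tissue.

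The difference between STIC and FOXJ1neg epithelium goes with a difference in depth in 6 of 6 pairs and a lower floor share in 4 of 6 (mean change -4.7 ± 5.41 points, SD), and 3 technical explanations were tested. In benign regions of the 4 donors outside the comparison (n = 32), the score of the higher probes changed by -0.0158 ± 0.0169 per log2 of depth within donor and region type (SE), and that of the lower probes by -0.02 ± 0.0368. At the mean log2 depth ratio of the pairs, 3.42, these slopes give -0.0539 (95% bounds -0.174 and 0.0658) and -0.0682 (-0.329 and 0.192), where the scores changed by 1.07 and -1.34. These values do not decide on depth. The slopes come from scores scaled over the benign regions alone, and the changes from scores scaled over all sums. Low counts, and with them the scores, respond to depth differently in these scalings. The shallowest FOXJ1neg sum (47802 counts) scored 2.39 for the lower probes, where FOXJ1neg averaged 1.05 ± 0.565 (SD, n = 10). Depth also varied less within a donor and region type (median range 1.27 log2) than between the pairs. Thinning cannot test depth either, since it leaves the expected ratios as they are. With the floor as a term, 81.1% of the higher probes kept their direction with an unadjusted p under 0.05. The median change of the higher probes went from 1.13 to 0.708, with 35 still past the adjusted threshold, so background may account for part of their size. The higher and lower probes were picked in these same sums, which favours keeping a direction, so background is not excluded. All 52 lower probes (100%) kept their direction with an unadjusted p under 0.05, with a median of -1.20 against -1.03. Stromal RNA in the FOXJ1neg regions would bring stromal probes along, and the 25% of the stromal set with the largest excess in metastases changed by a median of -0.0796 in STIC. The whole set had a mean score of 0.722 in metastasis stroma, 0.163 in normal stroma and -0.167 in FOXJ1neg epithelium. It comes from omentum, so its change cannot decide on stromal RNA of the tube.

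The difference in STIC change between the series was tested itself and passed 361 probes, 353 of them with the higher signed change in the STIC series. A fall in background would shift every abundant probe together, and the probes at or above a mean log2 CPM of 8 had a median difference of -0.919 (SD 0.743 over probes), against -1.70 for the 353 probes and -2.2 for the 15 of these at or above that limit. With the floor as a term 2 probes passed. The floor changes of the series do not overlap, so that term cannot separate background from series. The shift is 0.541 of the change of all called probes and 0.418 of that of the abundant ones, so a larger fall in background from FOXJ1neg to STIC in the STIC series stays open and is not shown to account for most of it. Probes picked in either STIC series donor against 2 HGSTIC donors had a median difference of 0.262 to 0.631 in the other donor against the other 2, over 12 such choices. That cannot decide on a single donor, since no matched lists were used and the abundant probes shifted the same way as a whole. A difference in biology between the series stays open and was not tested apart from background.

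Other splits of the same sums were fitted for each comparison except that of STIL, as swaps within donor pairs or as regroupings. Only the real split (1) gave as many probes in 3 comparisons, the smallest share that the splits allow, without adjustment over the comparisons. These are FOXJ1pos against FOXJ1neg (1435, highest other 1115, 100 of 512 splits drawn), STIC against FOXJ1neg (highest other 45, 32 splits) and epithelium against stroma in STIC (2432, highest other 1633, 100 splits drawn). This argues against chance in these 3 without excluding it. The share was not under 0.05 for the metastases, where the regroupings ignore the shared case numbers. As many probes came from 6 of 35 splits against invasive epithelium (real 1, highest other 96), from 5 of 84 against STIC (12, highest other 1809) and from 4 of 35 for stroma (15, highest other 626). The splits with 1809, 96 and 626 exchange 1 metastasis for 1 tube sum and point to structure among the sums other than the groups, and they do not follow a plate. The splits are too few for a share under 0.05 in the other designs. These are the p53 signature (real 1, highest other 6, 3 of 4 splits with as many), invasive against STIC epithelium (0, highest other 1, 8 of 8), STIC against normal stroma (30, highest other 18, 1 of 16), invasive against STIC stroma (11, highest other 30, 2 of 8) and the difference between series (361, highest other 100, 1 of 15).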

How the results depend on the processing

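The settings with thinning, a minimum sum, the floor or FOXJ1neg of the STIL plate only were added after the data were seen. The cause of a change was not tested, except that thinning leaves fewer probes to test and a left-out donor fewer sums. Numbers of passing probes, or percentages of the 18815 probes of the panel where marked, are listed in the order FOXJ1pos against FOXJ1neg (1435), p53 signature (1), STIL (18), STIC against FOXJ1neg (1.17%), invasive against STIC epithelium (0), metastasis against invasive (0.00531%, 1 probe) and against STIC epithelium (0.0638%), STIC against normal stroma (30), invasive against STIC stroma (11), metastasis against invasive stroma (0.0797%), epithelium against stroma (2432) and the difference between series (1.92%). DESeq2 gave 764, 1, 4, 1.31%, 13, 2.37%, 1.87%, 23, 3, 0.505%, 1957 and 0.925%. Limma on mean log2 CPM gave 454, 1, 0, 0.0106%, 0, 0%, 0.0106%, 0, 0, 0%, 612 and 0%. Upper quartile scaling moved metastasis against STIC to 0.117%, metastasis stroma to 0.244% and the series difference to 0.818%. Without a filter the p53 signature gave 4. With all regions, STIC gave 1.84%, metastasis stroma 0.138% and the series difference 1.11%. With subtraction of the floor the numbers were 640, 1, 0, 0.484%, 0, 0%, 0%, 6, 0, 0%, 860 and 0%, and with the floor as a term 77, 1, 35, 1.1%, 0, 0.537%, 2.03%, 6, 3, 5.07%, 65 and 0.0106%. With that term STIC turned from 0.898% higher and 0.276% lower to 0.229% and 0.872%, and RTS0027590 reversed in the series difference, to 2.92. The floor changes separate the series, so that term overlaps the difference tested there. Thinned sums gave 38, 0, 1, 0.117%, 1, 0%, 0.0425%, 7, 0, 0.0213%, 47 and 0.0106%. Sums of at least 100000 counts gave 4 for the p53 signature, 11 for STIL, 0.569% for STIC and 2 for invasive stroma. With no donor block FOXJ1pos gave 509, the p53 signature 2, STIC 0.26%, STIC stroma 0, invasive stroma 0 and epithelium against stroma 994, and invasive against STIC epithelium stayed at 0. Against FOXJ1neg of its plate STIL gave 4. Fitted over all sums of a compartment, FOXJ1pos gave 564, STIL 0, STIC 4.94%, invasive epithelium 19, STIC stroma 12 and invasive stroma 36. The block by shared case number gave 4.1% and 0.542% for the epithelium of metastases and 0.553% for their stroma, and plate as a term left 0.00531%, 0.0319% and 0.0159%. Leaving out 1 donor gave 790 to 1430, 1 to 4, 1 to 30, 0.33 to 1.37%, 0 to 1, 0 to 0.0478%, 0.0106 to 0.239%, 11 to 33, 0 to 90, 0.00531 to 0.622%, 1269 to 2436 and 0.0106 to 2.25%. The random donor block for STIL could not be estimated and the gene list tests were not run. Among the main fits, STIC against normal stroma had the fewest probes to test, 1780.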

Other observations

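The tests here were chosen after the data were seen. Probes of the ciliated side of the tube epithelium were followed into the lesions. The 305 probes higher in FOXJ1pos than in FOXJ1neg in the 4 donors without STIC were lower in STIC than in FOXJ1neg in 5 of 6 donors (score change -0.186 ± 0.225 SD, exact permutation p = 0.125, adjusted p = 0.271), with 38% of them higher. The donor with the largest change (-0.537) has a FOXJ1neg sum of a single shallow region, and without that donor the mean was -0.116 ± 0.163, lower in 4 of 5. Their score averaged 1.08 ± 0.253 in FOXJ1pos (n = 10), 0.0619 ± 0.179 in FOXJ1neg (n = 10) and -0.1 ± 0.0628 in STIC (n = 8). The 4 donors that defined the set are among these 10, so the gap between FOXJ1pos and FOXJ1neg is partly set by the choice of probes. In the p53 signature, 482 such probes from the 7 donors without one did not separate from FOXJ1neg (score change 0.00483 ± 0.182, n = 3 pairs, 52.5% higher).

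The p53 signature passed a single probe, yet the 52 probes lower in STIC leaned the same way in it, which gives a hypothesis of a change shared by both lesions. Their median change was -0.318 in the 3 pairs, lower in 3 of 3, at percentile 0.04 of matched random lists, and -0.308 without RTS0029686. Less stromal RNA in the p53 signature regions is a candidate explanation, as the stromal set was also lower in 3 of 3 pairs (score change -0.102 ± 0.0723). Without the probes higher in metastasis stroma the median of the other 41 was -0.337. The probes removed were called in 3 pairs of omentum, so stromal RNA of the tube stays open. With 3 pairs an exact permutation test cannot go under 0.25, so the donors do not decide whether the change is shared.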
